A study of Homo sapiens with 6 samples.

How the data were processed

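RNA from human umbilical vein endothelial cells was measured on 6 Affymetrix oligonucleotide arrays, 3 after control siRNA and 3 after siRNA against COUP-TFII. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells grown in endothelial medium received duplexes at 50 nM, total RNA was taken at 48 hours with Trizol, and biotin-labelled cRNA was made from it by a T7 oligo(dT) method. The value table held 1 intensity per probe set and array on a linear scale, as deposited by the authors, already at a common level. The software for summarising probes and scaling arrays was not given in the sources used here, so its effect on low intensities stays unknown. A second deposited table held the same intensities for the probe sets that the authors listed as differentially expressed, with no fold change or p-value. Its values were used to find the direction of each listed probe set and the size of its fold between group means, and for no call.

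Of 54675 probe sets, 62 control probe sets were left out. Of the remaining 54613, 41091 carried 1 gene symbol in the platform annotation, 1801 several and 11721 none. For 41037 of the 41091 the gene was found by its gene identifier in the RefSeq gene table of assembly GRCh38.p14, used for names only, and 54 kept the symbol of the annotation. No symbol needed an update. No coordinates are printed, since the tables name no genome build. Only probe sets with 1 symbol were used, and they covered 19775 genes.

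Intensities were transformed as log2(intensity + 16). Array medians differed by at most 0.0504 on the log2 scale, under the limit of 0.2 set for further scaling, so no scaling was added. A fold change on this scale understates the change of dim genes. Each gene was represented by the probe set with the highest mean over the 6 arrays. Genes whose probe set lay in the lowest 40% of all probe sets by mean were left out, which set a bound of 6.49 on the log2 scale (74.0 intensity units) and left 14575 genes. The bound is a percentile of the signal and not a detection limit. For a named gene with a group mean below it, the mean of the other group was set against the bound and the change is printed as at least that fold. The median standard error of a log2 fold change was 0.0986. Of 1479 called genes with over 1 probe set above this bound, 330 had a probe set of the opposite sign.

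The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, two-sided, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05 over all genes tested. "Rose", "fell" and "changed" are used of genes past this threshold. The 20 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists, and counted again with members adjusted over the list alone. Lists with under 5 tested members would have had counts only. The lists, the tests, the rule for named genes and all but 1 of the alternative settings were written before the data were examined. The lists were venous, lymphatic, arterial and pan-endothelial genes, Notch pathway, G1/S and DNA replication, mitosis, cyclin-dependent kinase inhibitors, p53 targets, inflammatory and adhesion genes, interferon-stimulated genes, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and amino acid stress, TGF-beta and BMP response, angiogenesis and tip cells, nuclear receptors, and markers of smooth muscle cells and fibroblasts, of blood cells and of epithelium. They share some members, such as CDKN1A, POSTN, NRP2, CXCR4 and EFNB2.

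The rule for named genes took the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap, up to 4 members past the threshold with the largest change from each list, and 19 genes of interest whatever their result, of which 17 were tested (1 lay below the bound on dim probe sets and 1 had no annotated probe set). The rule gave 94 genes. Of these, 9 whose calls were all lost without control array 2 were described together, apart from their lists, after their values were seen. The level of the targeted transcript is not reported here.

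Replicate numbers are shared between the groups, and the labels do not say what a number stands for. Deviations from the group mean correlated between same-numbered arrays with Pearson's r of 0.311, 0.168 and 0.578 across genes (Spearman's rho 0.267, 0.0836 and 0.458), where genes are not independent replicates. All 3 Pearson values were above 0.1, so the numbers were taken to pair the arrays. Control array 2, however, correlated more with COUP-TFII siRNA array 1 (0.234) than with array 2, and control array 1 with COUP-TFII siRNA array 2 gave 0.156. Deviations from a group mean cancel out within the group, so a match of the arrays numbered 3 raises the other values. The correlations therefore show that the arrays numbered 3 stand apart, but cannot tell how arrays 1 and 2 of the groups pair. The planned comparison without the block stayed the main one, and the value with the replicate number as a block stands beside a result whose call it changed. Differences within same-numbered pairs were used to describe the arrays.

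The alternatives for values were quantile normalization, median scaling, pseudocounts of 1 and 64, and no bound on dim probe sets or one at the lowest 60%. Others were the mean of a gene's probe sets and only probe sets without a letter suffix. A letter suffix, such as _s_at, _a_at or _x_at, does not by itself show cross-hybridisation, and a probe set without one is not taken as the better one. Further alternatives were eBayes without a trend or with a robust one, the replicate block, a fold of at least 1.5 and leaving out each array. For lists they were an estimated correlation in camera, and fry, which tests a list without comparing it with other genes. The estimated correlation rests on the few residual degrees of freedom of the fit, so a list it does not call is not taken as unchanged. Leaving out both arrays of a number was added after the data were seen. The listed probe sets were also compared over all probe sets without a bound. Shares have exact binomial 95% intervals, which cover counting error only.

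The fit was tested on simulated data for the comparison of the 2 groups, with 14575 genes of which 200 were changed by known amounts. It called 43% of those changed by 0.5 on the log2 scale and 92% of those changed by 1, with 11 unchanged genes called. It called 0 genes where nothing had been changed. The simulated genes varied independently, with no shared effect of replicate number, and the arrays themselves gave 2640 calls. The shares therefore hold for the simulated setting only. Levels of the Y chromosome and of X inactivation transcripts were left out of all per-array values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.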

Results

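Transcript levels were measured on 6 oligonucleotide arrays hybridised with RNA from human umbilical vein endothelial cells (HUVEC), primary cells from the wall of the umbilical vein. The cells had received control siRNA (3 arrays) or siRNA against COUP-TFII (3 arrays). COUP-TFII is an orphan nuclear receptor of venous endothelium with a known part in keeping Notch signalling low in veins. The duplexes were used at 50 nM and RNA was taken 48 hours later. Array medians lay between 95.7 and 99.6 intensity units, and the number of arrays limits the precision of every value. Spearman correlations across probe sets were 0.985 to 0.990 within groups and 0.978 to 0.987 between groups. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical. Whether the siRNA lowered its target was not analysed here.

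The comparison of COUP-TFII siRNA with control siRNA asks which transcripts of venous endothelial cells differ once the receptor is targeted. Genes of DNA replication and mitosis were lower, and genes of the interferon response, p53 targets, Notch and arterial genes and TGF-beta response genes were higher by limma's camera with a preset correlation between genes. All of these list calls were lost by camera with an estimated correlation (adjusted p = 0.343 to 0.552). That version rests on few residual degrees of freedom and called 0 of the 20 lists, so it cannot tell whether a list changed. Besides, 34 of 44 interferon, 19 of 27 arterial and 23 of 34 Notch genes did not pass one by one. LHX6, a LIM homeobox transcription factor, and DIRAS3, a Ras-related GTPase, had the largest decreases, and PPARA, a nuclear receptor that controls fatty acid oxidation, had the largest increase among genes whose groups did not overlap. Of 14575 genes tested, 1512 rose and 1128 fell by limma with Benjamini-Hochberg adjustment, 18.1% of those tested. Of these, 127 rose and 72 fell at least 2-fold. The groups did not overlap for 5169 genes (35.5%), where chance gives 10% for 3 arrays against 3. With the replicate number as a block, 2123 genes rose and 1715 fell, and 1511 and 1126 of them were the genes called without the block. Without control array 1 the counts were 812 and 383, and without control array 2 they were 721 and 382.

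The largest increases included a nuclear receptor, secreted protease inhibitors and an integrin subunit. PPARA stood at 6.78 ± 0.31 on control arrays (mean ± SD of log2(intensity + 16), n = 3) and rose by 2.21 ± 0.15 (log2 fold change ± SE, limma adjusted p = 0.000164), which is 4.63-fold. PLAAT3, an enzyme of phospholipid metabolism, rose by 2.07 ± 0.15 (SE). The cystatins CST1 and CST4, inhibitors of cysteine proteases, rose by 2.04 ± 0.20 and 1.86 ± 0.20. C1QTNF6 rose by 2.01 ± 0.14, and the anthrax toxin receptor gene ANTXR1 rose by 1.98 ± 0.21. For ANTXR1, 1 of 4 probe sets had the opposite sign, and the probe set chosen without COUP-TFII siRNA array 1 or 2 gave 0.17 (limma adjusted p = 0.504) and 0.19 (adjusted p = 0.435). CYTL1, which encodes a secreted cytokine-like protein, rose from 9.60 ± 0.12 to 11.57 ± 0.05 (SD), by 1.97 ± 0.09 (SE, limma adjusted p = 2.19e-05). WIPI1, which acts in autophagosome formation, rose by 1.95 ± 0.15. HPSE, the heparan sulfate-cleaving heparanase, rose by 1.91 ± 0.20, and the integrin subunit gene ITGB3 rose by 1.83 ± 0.18. Limma adjusted p-values of these 10 genes lay between 2.19e-05 and 0.000822. Each was higher in all 3 same-numbered pairs of arrays, which follows from choosing genes whose groups did not overlap. On the mean of their probe sets PPARA, ITGB3 and ANTXR1 rose by 1.07, 0.93 and 0.58. ITGB3 rose by 0.48 on a probe set without a letter suffix.

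The largest decreases included a transcription factor, a small GTPase and an integrin subunit. LHX6 fell from 9.22 ± 0.19 (SD, n = 3 arrays) to a mean of 6.29, below the bound of 6.49 on dim signal, and so at least 6.62-fold when set against that bound (limma adjusted p = 2.19e-05). DIRAS3 changed by -2.76 ± 0.29 (SE), and PLAC8 by -2.27 ± 0.28. ITGB8, which encodes an integrin subunit, changed by -2.08 ± 0.11 (SE, limma adjusted p = 5.4e-05). The glypican gene GPC5 also fell from 7.57 to a mean below the bound, by at least 2.11-fold against it (limma adjusted p = 0.000922). ALDH1A1, a retinaldehyde dehydrogenase, changed by -1.90 ± 0.41. PGM2L1, PHTF2 and FSTL5 changed by -1.78 ± 0.14, -1.77 ± 0.22 and -1.72 ± 0.25. MARVELD2, the tight junction protein tricellulin, changed by -1.71 ± 0.17. The highest limma adjusted p of these 10 genes was 0.0139, for ALDH1A1. Each was lower in all 3 same-numbered pairs of arrays, which again follows from the choice of genes without overlap. On the mean of their probe sets ITGB8, PGM2L1 and PHTF2 changed by -1.26, -1.15 and -0.72. The call of ALDH1A1 was lost with a robust variance trend (limma adjusted p = 0.0806).

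**Figure D1:**
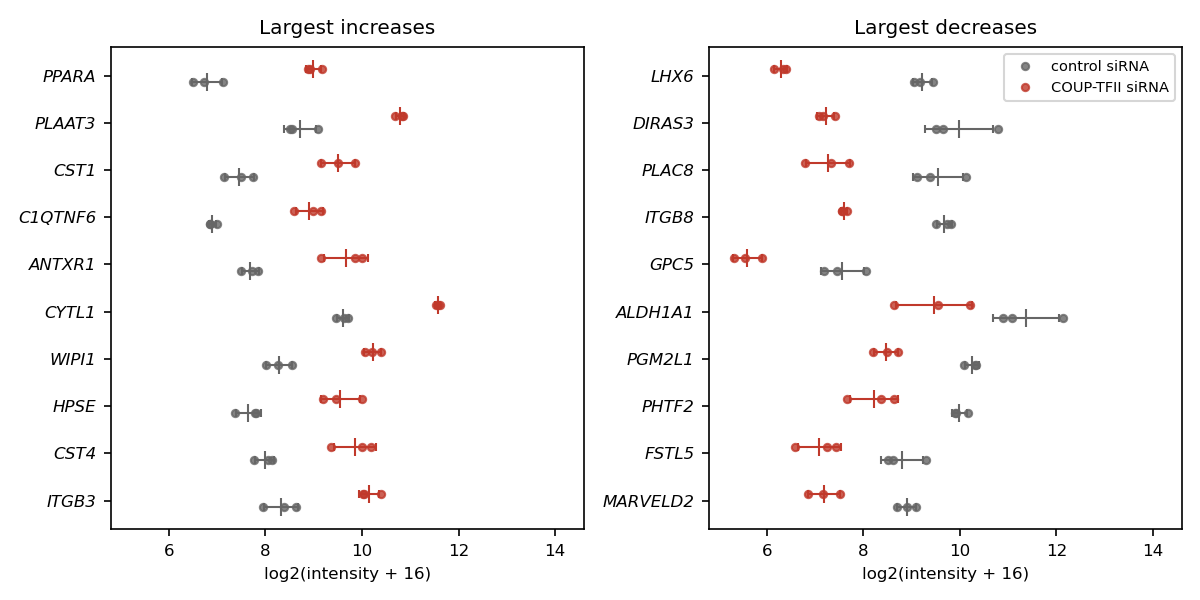
Log2(intensity + 16) on each array (points) for the 10 largest increases (left) and decreases (right), with the group mean (tick) and SD (bar) of 3 arrays for control siRNA in grey and COUP-TFII siRNA in red. The groups do not overlap for any of these genes, by the rule that chose them. LHX6 falls from 9.22 to below the bound of 6.49 on dim signal, as GPC5 does from 7.57.

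Genes of the cell cycle were lower after COUP-TFII siRNA. Of 74 mitosis genes tested, 61 fell, none rose and 13 did not pass, and all 74 had a negative difference, with a median of -0.69 on the log2 scale. Of 62 genes of the G1/S transition and DNA replication, 32 fell, none rose and 30 did not pass, with a median of -0.50. By limma 0 genes of either list were higher even at an unadjusted p under 0.05. Adjusted over the list alone, 70 and 46 genes fell. The kinesin genes KIF23, KIF2C and KIF11, whose products move chromosomes and spindle parts, changed by -1.02 ± 0.28, -0.98 ± 0.19 and -0.96 ± 0.25 (SE, n = 3 arrays per group), and the kinetochore gene SPC24 by -0.95 ± 0.17. The replication genes ORC6, POLE2 and GINS2 changed by -1.02 ± 0.21, -0.99 ± 0.25 and -0.98 ± 0.23, and the cyclin gene CCNE2 by -1.01 ± 0.20. A probe set of GINS2 without a letter suffix gave 0.09, and the mean of its probe sets -0.44 (limma adjusted p = 0.0657). SPC24 changed by -0.52 on the mean of its probe sets. Limma's camera placed both lists below other genes, with an adjusted p of 1.28e-25 for mitosis and 6.44e-17 for replication. These calls were lost with gene correlations taken from the data (adjusted p = 0.343 with an estimated correlation for each list), and that of mitosis genes also by limma's fry (adjusted p = 0.0590). With an estimated correlation limma's camera called 0 of the 20 lists, of which 2 had an unadjusted p under 0.05. This version rests on the few residual degrees of freedom of the fit. Its unadjusted camera p was 0.154 for mitosis genes, all of which were lower, and 0.0201 for arterial genes, with a median of 0.17. It had little power here, so a call lost with it neither shows nor excludes a change of the list.

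The size of the cell cycle decrease differed between arrays. Same-numbered pairs gave median differences of -0.49, -1.11 and -0.47 for mitosis genes and of -0.34, -0.89 and -0.30 for replication genes. The count of mitosis genes that fell was 9 without control array 1 and 7 without control array 2, and that of replication genes was 8 and 6. Fewer arrays remain in these fits, and ORC6, POLE2 and KIF11 still differed by -0.95, -0.93 and -0.90 without control array 1. With the replicate block 68 mitosis and 44 replication genes fell. With both arrays numbered 1 left out, 32 mitosis and 9 replication genes fell, and with both numbered 2 left out, 6 and 16 fell. Without control array 1 the limma adjusted p was 0.131 for KIF23, 0.101 for KIF11, 0.0547 for ORC6, 0.0931 for POLE2 and 0.0739 for GINS2, and without control array 2 it was 0.130, 0.10, 0.0584, 0.0930 and 0.0738. The call of CCNE2 was lost without control array 2 (limma adjusted p = 0.0517), and that of KIF23 also without COUP-TFII siRNA array 2 (0.0882) or 3 (0.0714) and with a robust variance trend (0.0638). POLE2 changed by -0.66 without COUP-TFII siRNA array 2. E2F1, a transcription factor of S phase entry, differed by -0.17 ± 0.09 (limma adjusted p = 0.234). On a probe set without a letter suffix E2F1 differed by -0.91 (limma adjusted p = 0.0014), and on the mean of its probe sets by -0.54 (0.00562). CDK2 differed by -0.37 ± 0.13 (limma adjusted p = 0.0818, 0.0429 with the replicate block and 0.0476 after quantile normalization), and CCND1 by -0.16 ± 0.11 (adjusted p = 0.391).

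Several p53 targets rose. Of 26 tested, 14 rose, 1 fell and 11 did not pass, with a median of 0.38, and adjusted over the list alone 16 rose and 2 fell. TP53I3 rose by 1.29 ± 0.14 (SE, n = 3 arrays per group), SPATA18 by 1.07 ± 0.16, GDF15, a secreted stress cytokine, by 0.82 ± 0.19, and the ribonucleotide reductase subunit gene RRM2B by 0.80 ± 0.11. Limma's camera gave an adjusted p of 2.5e-05 for the list, and the call was lost at adjusted p = 0.343 with an estimated correlation. The number that rose was 7 without control array 1 and 7 without control array 2. GDF15 lost its call without control array 1 (limma adjusted p = 0.0734) or 3 (0.0528). Of 10 cyclin-dependent kinase inhibitor and pocket protein genes, 2 rose, 1 fell and 7 did not pass, and adjusted over the list alone 3 rose and 2 fell (limma's camera adjusted p = 0.379 for the list). CDKN1A, which encodes p21 and is itself a p53 target, rose by 0.80 ± 0.11 (limma adjusted p = 0.00199). CDKN1C rose from a control mean below the bound on dim signal (6.37) to 7.22, at least 1.66-fold against that bound (limma adjusted p = 0.0330), and RBL1 changed by -0.75 ± 0.21. Without control array 1 or 2 the limma adjusted p was 0.121 and 0.108 for CDKN1C and 0.129 and 0.106 for RBL1. CDKN1C also lost its call without COUP-TFII siRNA array 2 (0.0558) and with a robust variance trend (0.0572), and its fitted difference was 0.56 without array 3 of that group and 0.85 with it. RBL1 lost it on the mean of its probe sets (limma adjusted p = 0.0965), without a variance trend (0.0508) and without control array 3 (0.0612) or COUP-TFII siRNA array 2 (0.0607) or 3 (0.0626).

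Interferon-stimulated genes lay above the control mean on COUP-TFII siRNA arrays 1 and 2, with medians of 1.72 and 1.67, and below it on array 3, with a median of -0.28. Control array 3 lay at -0.43. Of 44 tested, 43 had a positive difference, with a median of 0.99, but 10 rose, none fell and 34 did not pass, and adjusted over the list alone 10 rose. By limma 21 were higher and 0 lower at an unadjusted p under 0.05. Same-numbered pairs gave median differences of 1.39, 1.41 and 0.23, and 29, 33 and 2 genes differed by more than 1. The arrays numbered 3 also stood apart from the others on the second principal component, which held 19.6% of the variance. IFI27 rose by 1.19 ± 0.30 (SE, n = 3 arrays per group) and differed by 1.15, 1.20 and 1.21 in the 3 pairs. BST2, which tethers budding viruses, rose by 1.49 ± 0.42, SAMD9L by 1.41 ± 0.34 and RIGI, a sensor of double-stranded RNA, by 1.37 ± 0.37. With the replicate block 36 genes rose, without a variance trend 6, and with a robust variance trend 4, where BST2, RIGI, IFI27 and SAMD9L lost their calls (limma adjusted p = 0.164, 0.113, 0.142 and 0.0640). BST2 and RIGI also lost them on the mean of probe sets (0.0518 and 0.0523), and BST2 without a variance trend (0.0574). By limma's camera the list had an adjusted p of 2.6e-07 (5.49e-15 with the block), and the call was lost at adjusted p = 0.552 with an estimated correlation and 0.246 by fry. The median was 0.65 without COUP-TFII siRNA array 2 and 1.73 without array 3. The number that rose was 1, 2 and 3 without control array 1, 2 and 3, and 1, 2 and 41 without COUP-TFII siRNA array 1, 2 and 3, and with both arrays numbered 1, 2 or 3 left out it was 0, 1 and 43 (8 were higher at an unadjusted p under 0.05 by limma without number 1). BST2, SAMD9L and RIGI each lost the call on leaving out any single array other than COUP-TFII siRNA array 3 (limma adjusted p from 0.0557 for SAMD9L to 0.114 for BST2), and IFI27 without control array 1 (0.0562) or COUP-TFII siRNA array 1 (0.0762) or 2 (0.0712).

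Of 31 inflammatory and adhesion genes, 4 rose, 1 fell and 26 did not pass, also adjusted over the list alone, and the median was 0.11. The chemokine gene CXCL6 rose by 1.28 ± 0.11 (SE, limma adjusted p = 0.000395) and IL6 by 0.89 ± 0.21, while the adhesion molecule gene VCAM1 changed by -0.71 ± 0.15. Limma's camera gave an adjusted p of 0.0888 for the list, and 0.0194 with the replicate block, under which 12 genes rose and 3 fell. On all 6 arrays it was 0.663 with an estimated correlation and 0.237 by fry. With the preset correlation the camera adjusted p was 0.0258 without control array 1, 0.0133 without control array 2 and 0.00233 without COUP-TFII siRNA array 3, where 10 genes rose, but 0.692 without control array 3 and 0.153 and 0.330 without COUP-TFII siRNA array 1 and 2. Without control array 2, 2 genes rose. VCAM1 lost its call without control array 1 (limma adjusted p = 0.0592) or 2 (0.0694), and IL6 without control array 2 (0.0646) or COUP-TFII siRNA array 1 (0.0523).

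**Figure D2:**
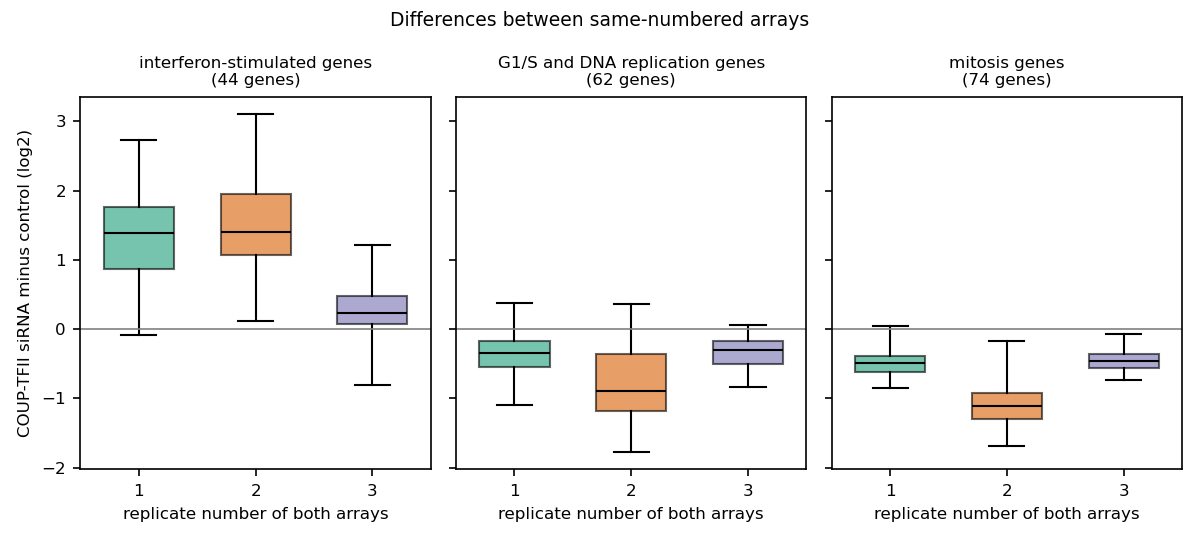
Differences between same-numbered arrays (COUP-TFII siRNA minus control, log2) for the members of 3 gene lists, with the box showing quartiles and median and the whiskers the full range over genes. Interferon-stimulated genes have medians of 1.39, 1.41 and 0.23, and mitosis genes of -0.49, -1.11 and -0.47.

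Genes typical of arteries and of the Notch pathway were higher after COUP-TFII siRNA. Of 27 arterial endothelial genes tested, 7 rose, 1 fell and 19 did not pass, with a median of 0.17. Of 34 Notch pathway genes, 10 rose, 1 fell and 23 did not pass, also with a median of 0.17. Adjusted over the list alone, 11 rose and 2 fell in each list. NOTCH4, an endothelial Notch receptor, rose from 8.13 ± 0.08 to 9.25 ± 0.23 (SD), by 1.12 ± 0.13 (SE, limma adjusted p = 0.000976). EFNB2, the arterial ephrin, rose by 0.74 ± 0.12 (adjusted p = 0.00505 by limma), FBLN5, an elastic fibre protein gene, by 1.27 ± 0.09 and the chemokine receptor gene CXCR4 by 1.08 ± 0.23. HES2 and NCSTN, the latter a gamma-secretase subunit gene, rose by 0.75 ± 0.13 and 0.74 ± 0.09. NRARP, a Notch target that limits Notch signalling, fell 2.0-fold (limma adjusted p = 0.00114). HES1, a Notch target named after its value was seen, rose by 0.63 ± 0.09 (limma adjusted p = 0.00248). On the mean of its probe sets NOTCH4 rose by 0.66. By limma's camera the lists had adjusted p-values of 0.00288 for arterial and 0.0200 for Notch genes, and both calls were lost at adjusted p = 0.343 with an estimated correlation.

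Other known Notch genes did not pass. The ligand gene DLL4 differed by 0.16 ± 0.09 (limma adjusted p = 0.292) and the receptor gene NOTCH1 by -0.21 ± 0.11 (adjusted p = 0.263). The Notch target genes HEY1 and HEY2 differed by 0.36 ± 0.19 (limma adjusted p = 0.231, and 0.0408 with the replicate block) and 0.51 ± 0.16 (0.0630, and 0.00408 with the block). HEY2 passed without COUP-TFII siRNA array 2 (limma adjusted p = 0.0232) and after quantile normalization (0.0479). It also passed by limma on the mean of its probe sets (adjusted p = 0.0135) and on those without a letter suffix (0.0018). JAG1 differed by 0.31 ± 0.25 (limma adjusted p = 0.467, and 0.0107 with the block). With the replicate block 13 arterial genes rose, and without control array 2 the number of Notch genes that rose was 6. With both arrays numbered 1 or 2 left out, 3 and 5 Notch genes rose.

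Venous, lymphatic and pan-endothelial genes went both ways. Of 11 venous endothelial genes tested, 2 rose, 3 fell and 6 did not pass, and 3 rose and 3 fell adjusted over the list alone. EPHB4, the venous ephrin receptor, changed by -0.70 ± 0.14 (SE, limma adjusted p = 0.00968) and NRP2, a co-receptor of VEGF-C, by -0.48 ± 0.10, while NT5E and POSTN rose by 0.97 ± 0.10 and 1.16 ± 0.15. NRP2 differed by -0.15 on the mean of its probe sets (limma adjusted p = 0.292) and by -0.26 with both arrays numbered 1 left out (0.417). It also lost its call without control array 2 (limma adjusted p = 0.0603), where 1 venous gene fell. Of 14 lymphatic endothelial genes, 1 rose and 2 fell, also adjusted over the list alone, and 3 rose with the replicate block. Without control array 2, 0 rose and 0 fell by limma, with 2 higher and 2 lower at an unadjusted p under 0.05. Without control array 3, 0 rose and 1 fell, and without COUP-TFII siRNA array 1, 0 rose, again with 2 higher at an unadjusted p under 0.05 by limma. GATA2, an endothelial transcription factor, changed by -0.60 ± 0.15, and lost its call without control array 1 (limma adjusted p = 0.0924), 2 (0.0589) or 3 (0.0698), and it changed by -0.37 on the mean of its probe sets. The lymphatic regulator gene PROX1 differed by 0.05 ± 0.18 (limma adjusted p = 0.901) and LYVE1 by 0.57 ± 0.32 (0.270, and 0.00364 with the block). NRP1 differed by -0.14 ± 0.08 (limma adjusted p = 0.295), with the opposite sign in 2 of 3 probe sets.

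Of 34 pan-endothelial genes tested, 3 rose, 6 fell and 25 did not pass, and 4 rose and 7 fell adjusted over the list alone. The VEGF receptor genes moved apart, FLT1 rising by 0.88 ± 0.15 (SE, limma adjusted p = 0.00535) and KDR changing by -0.52 ± 0.14 (adjusted p = 0.0345). The tight junction gene CLDN5 changed by -0.45 ± 0.12. Without control array 1, 2 or 3 the limma adjusted p was 0.102, 0.131 and 0.0532 for KDR and 0.0556, 0.139 and 0.0652 for CLDN5. Without COUP-TFII siRNA array 1 it was 0.0733 for KDR and 0.0983 for CLDN5, and without array 3 of that group 0.0792 for CLDN5. Limma's camera gave adjusted p-values of 0.827 for venous, 0.713 for lymphatic and 0.713 for pan-endothelial genes. The medians were -0.0057, 0.03 and 0.01 and the means 0.03, -0.0062 and -0.02, while the camera direction was down for all 3 lists. The number of pan-endothelial genes that fell was 3 without control array 1, 2 without control array 2 and 3 without COUP-TFII siRNA array 1, and 5 rose with the replicate block.

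Genes of the TGF-beta and BMP response and of angiogenesis were higher. Of 29 TGF-beta and BMP response genes tested, 13 rose, 2 fell and 14 did not pass, with a median of 0.25, and adjusted over the list alone 15 rose and 4 fell. TGFBR1, a TGF-beta receptor gene, rose from 8.28 ± 0.08 to 9.78 ± 0.42 (SD, n = 3 arrays each), 2.83-fold (limma adjusted p = 0.0014). TGFB1 rose by 1.06 ± 0.11, but the mean of its probe sets rose by 0.44 and a probe set without a letter suffix gave -0.17. SMAD6 and ID2, which limit and mediate BMP signalling, rose by 0.84 ± 0.13 and 0.83 ± 0.14. Of 34 angiogenesis and tip cell genes, 12 rose, 3 fell and 19 did not pass, with a median of 0.16, and adjusted over the list alone 13 rose and 3 fell. Besides ITGB3, CXCR4 and FLT1, the protease gene ADAMTS1 rose by 1.49 ± 0.26. By limma's camera the lists had adjusted p-values of 0.000666 and 0.0125, and both calls were lost at adjusted p = 0.343 with an estimated correlation. With probe sets restricted to those without a letter suffix, the camera adjusted p was 0.128 and 0.118. The median of TGF-beta and BMP response genes was then 0.15. Without control array 2, 8 TGF-beta and BMP response genes rose, and 7 angiogenesis genes rose and 1 fell. With both arrays numbered 1 left out, 6 genes of each list rose, and with both numbered 2 left out, 8 and 6 rose. With the replicate block 4 TGF-beta and BMP response genes fell.

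Of 30 nuclear receptor genes tested, 3 rose, 1 fell and 26 did not pass (limma's camera adjusted p = 0.257, median 0.05), and adjusted over the list alone 3 rose and none fell. NR2F1, the closest relative of COUP-TFII, rose from 10.76 ± 0.09 to 11.37 ± 0.09 (SD, n = 3 arrays each), by 0.60 ± 0.08 (SE, limma adjusted p = 0.00171). PPARA had the largest change of the list.

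Of 20 cholesterol synthesis genes tested, 3 fell, none rose and 17 did not pass, also adjusted over the list alone, with a median of -0.18. By limma 6 were lower and 0 higher at an unadjusted p under 0.05. MSMO1, a sterol oxidase gene, changed by -0.94 ± 0.20 (SE, limma adjusted p = 0.014) and the sterol isomerase gene EBP by -0.46 ± 0.09, but EBP differed by -0.27 on the mean of its probe sets (adjusted p = 0.0982), 1 of which had the opposite sign. Same-numbered pairs gave list medians of -0.019, -0.089 and -0.41, and the median was -0.021 without control array 3 and -0.047 without both arrays numbered 3. Limma's camera gave an adjusted p of 0.0204 for the list, and the call was lost at adjusted p = 0.663 with an estimated correlation and 0.411 by fry. The camera adjusted p was 0.648 without control array 3, 0.0622 without COUP-TFII siRNA array 1, 0.0695 without array 2 of that group and 0.135 without both arrays numbered 3. With the replicate block 6 genes fell.

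Of 36 hypoxia and glycolysis genes tested, 6 rose, 2 fell and 28 did not pass, also adjusted over the list alone, with a median of 0.07. BNIP3L, a mitophagy receptor gene, rose by 1.10 ± 0.18 (SE, limma adjusted p = 0.00389) and MXI1 by 0.59 ± 0.15. ADM, the vasodilator adrenomedullin and a well-known hypoxia target, changed by -1.04 ± 0.11 (limma adjusted p = 0.000742). By limma's camera the list had an adjusted p of 0.0358, and the call was lost at adjusted p = 0.343 with an estimated correlation. It was also lost by camera after quantile normalization (adjusted p = 0.0881) and on probe sets without a letter suffix (0.280). Without control array 3 (camera adjusted p = 0.0595) or COUP-TFII siRNA array 1 (0.0783) or 2 (0.0949) the call was lost too. The median was 0.048 after quantile normalization, 0.042 on probe sets without a suffix, and 0.11 and 0.12 without control array 1 and COUP-TFII siRNA array 1. The number that rose was 1, 1 and 3 without control array 1, 2 and 3, and 3 and 2 without COUP-TFII siRNA array 1 and 2. MXI1 lost its call without control array 1 (limma adjusted p = 0.0998) or 2 (0.101) or COUP-TFII siRNA array 3 (0.0511).

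Of 32 genes of the unfolded protein and amino acid stress responses, 3 rose, none fell and 29 did not pass, with a median of 0.11, and adjusted over the list alone 2 rose. Same-numbered pairs gave medians of -0.031, 0.27 and 0.099. By limma 10 were higher and 0 lower at an unadjusted p under 0.05. VLDLR, a lipoprotein receptor gene, rose from a control mean below the bound on dim signal (6.19) to 7.11, at least 1.54-fold against that bound (limma adjusted p = 0.00263), and ASNS, asparagine synthetase, rose by 0.68 ± 0.14 (SE). Limma's camera gave an adjusted p of 0.0204, and the call was lost at adjusted p = 0.701 with an estimated correlation and by fry (0.409). It was lost by camera with the lowest 60% of probe sets left out (adjusted p = 0.0671) and on probe sets without a letter suffix (0.213). On the latter 0 of 21 rose by limma and 3 were higher at an unadjusted p under 0.05. The camera call was also lost without control array 3 (adjusted p = 0.648) or COUP-TFII siRNA array 2 (0.308). The median was 0.028 and 0.040 without these arrays, and 0.26 and 0.25 without control array 1 and COUP-TFII siRNA array 3. With the replicate block 12 genes rose and 1 fell. The number that rose was 1 without control array 2 and 6 without COUP-TFII siRNA array 3. ASNS lost its call without control array 2 (limma adjusted p = 0.0539).

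Markers of other cell types showed small or mixed differences. None of 15 blood cell markers passed by limma, with 1 at an unadjusted p under 0.05 (limma's camera adjusted p = 0.713, median 0.02). Of 22 smooth muscle and fibroblast markers, 2 rose and 20 did not pass, also adjusted over the list alone (median 0.09, limma's camera adjusted p = 0.132, and 0.0404 without control array 1). Those that rose were POSTN and TAGLN, an actin-binding protein gene of contractile cells. TAGLN rose by 1.41 ± 0.16 (SE, limma adjusted p = 0.000992) but differed by 0.04 on a probe set without a letter suffix. Of 12 epithelial markers, 1 rose, 2 fell and 9 did not pass, also adjusted over the list alone (median -0.08, limma's camera adjusted p = 0.167). The keratin genes KRT18 and KRT8 changed by -0.97 ± 0.09 and -0.45 ± 0.08, and KRT19 rose by 0.63 ± 0.10. The 3′ minus 5′ signal of the actin control transcript, a sign of RNA degradation, was 0.24 ± 0.16 on control and 0.09 ± 0.10 on COUP-TFII siRNA arrays (SD, n = 3, two-sided exact permutation p = 0.3, where 0.1 is the smallest possible).

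**Figure D3:**
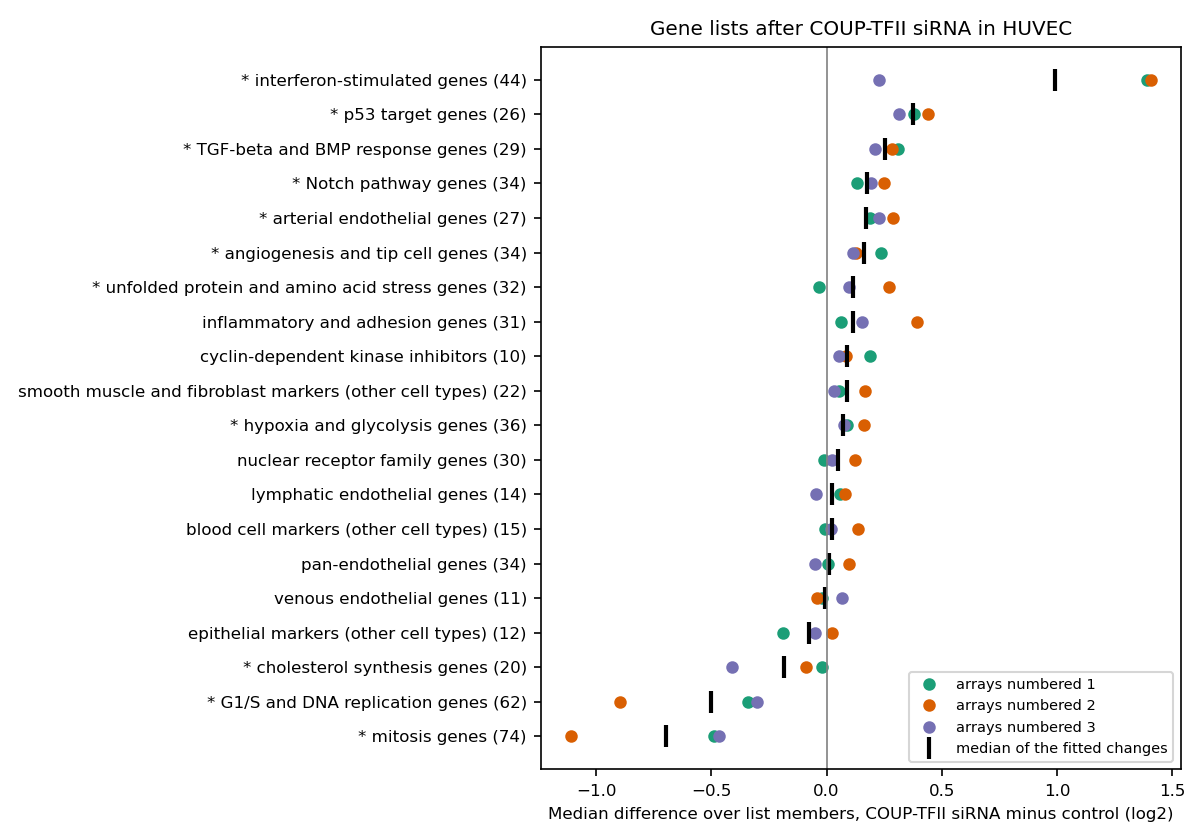
Median difference over the members of each gene list (COUP-TFII siRNA minus control, log2) for each same-numbered pair of arrays (points) and for the fitted changes (tick), with the number of genes tested in brackets and an asterisk where limma's camera passed with a preset correlation. Mitosis genes lie lowest at -0.69 and interferon-stimulated genes highest at 0.99, and no list passed with an estimated correlation.

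The 9 other genes taken from the lists passed by limma on all 6 arrays but not without control array 2, where fewer arrays remain. All 9 passed with the replicate block (limma adjusted p from 0.00258 for VEGFC to 0.0258 for NR1D2). IGFBP3, an arterial list gene for an IGF-binding protein, rose by 0.88 ± 0.26 (SE, n = 3 arrays per group), the chemokine gene CCL5 by 0.62 ± 0.14, the stress gene SESN2 by 0.56 ± 0.16, the lymphatic growth factor gene VEGFC by 0.44 ± 0.12, the collagen prolyl hydroxylase gene P4HA2 by 0.43 ± 0.11 and the retinoic acid receptor gene RARA by 0.39 ± 0.08. EGFL7, STARD4 and NR1D2, of the pan-endothelial, cholesterol and nuclear receptor lists, changed by -0.40 ± 0.11, -0.44 ± 0.11 and -0.41 ± 0.12. With control array 2 left out, the first group differed by 0.39 (RARA) to 0.78 (IGFBP3). The genes that fell then differed by -0.51 (STARD4) to -0.38 (EGFL7). Without control array 2 the limma adjusted p was 0.167 for IGFBP3, 0.0788 for CCL5, 0.110 for SESN2, 0.126 for VEGFC, 0.0876 for P4HA2, 0.0624 for RARA, 0.129 for EGFL7, 0.0581 for STARD4 and 0.148 for NR1D2. Without control array 1 the calls were also lost, apart from VEGFC (limma adjusted p from 0.0514 for CCL5 to 0.138 for IGFBP3). IGFBP3, VEGFC, STARD4, P4HA2, NR1D2 and SESN2 lost the call without control array 3 as well (limma adjusted p from 0.0542 to 0.114), these 6 and EGFL7 without COUP-TFII siRNA array 1 (0.0581 to 0.107), the same without IGFBP3 and EGFL7 on leaving out array 2 of that group (0.0514 to 0.0963), and IGFBP3 (0.0788) and EGFL7 (0.0838) on leaving out array 3, where IGFBP3 differed by 0.58. On the mean of probe sets RARA differed by 0.14 (limma adjusted p = 0.245), NR1D2 by -0.15 (0.471), P4HA2 by 0.27 (0.101), CCL5 by 0.68 (0.150) and SESN2 by 0.52 (0.0638). Without a variance trend the limma adjusted p was 0.0638 for IGFBP3, 0.0521 for EGFL7 and 0.0520 for SESN2, and it was 0.0795 for IGFBP3 with a robust one, 0.0611 for SESN2 after quantile normalization, 0.0541 for NR1D2 without a bound on dim probe sets and 0.255 for CCL5 on probe sets without a suffix.

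The authors' deposited list of differentially expressed probe sets was compared with these calls. By the group means of its values it held 1648 probe sets higher and 1247 lower after COUP-TFII siRNA, with fold sizes between linear group means from 1.26 to 9.36 and a median of 1.60. Of the 1971 tested genes with a listed probe set, 1659 (84.2%, exact binomial 95% interval 82.5 to 85.8%) passed limma in the same direction and 2 in the opposite one. Of the 2640 genes that passed here, 974 had no listed probe set. The listed probe sets differed by at least 49.7 intensity units and 1.26-fold between group means. The calls here had no such bounds, so the counts are not at like thresholds. The list was chosen by the authors on these same arrays, so the overlap is not independent evidence of direction.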

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

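All tests of explanations in this part were chosen only after the results were seen. Probe sets that carried several gene names or none were outside the comparison of genes. Of 5672 such probe sets above the bound on dim signal, 165 were higher and 159 lower after COUP-TFII siRNA by limma with Benjamini-Hochberg adjustment, a signal in data outside the main measurement. With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. Only 1 of the 10 splits, the real one, called 2640 genes, and the highest of the others called 0. Every other split puts arrays of both treatments on each side. A treatment effect then widens the spread within the sides, so these counts do not measure chance. For gene lists the real split called 11 and the highest of the others 9, again 1 of 10 splits as large. The other splits that part all 3 same-numbered pairs called 7, 0 and 4 lists and 0 genes each.

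Interferon-stimulated genes differed by a median of 1.48 over numbers 1 and 2, while at number 3 the median was 0.23. A share of blood cells that raises their markers as far at numbers 1 and 2 was argued against by 15 blood cell markers above the bound on dim signal. None of them was in another list, and their median difference there was 0.0127 and the largest 0.192. The markers CD79A and CD3D stood at 9.14 and 7.96 on all control arrays and at 9.16 and 7.94 on all COUP-TFII siRNA arrays. A signal this high on control arrays could hide a small share of blood cells, and markers below the bound were not used. A few blood cells were therefore not excluded. A response to transfected duplexes that does not need COUP-TFII could be a cause, since control arrays 1 and 2 also lay above control array 3 for 41 of the 44 genes, by a median of 0.647. It cannot be told apart from an effect of COUP-TFII itself with 1 targeting group, and the latter stays open as an untested hypothesis. What set the arrays numbered 3 apart was not tested.

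The 136 replication and mitosis genes had a median log2 fold change of -0.64. A trend with signal level was argued against by 10000 random lists matched on mean signal, whose medians lay between -0.10 and 0.10 with a median of 0.0034. At number 3 interferon-stimulated genes differed less, by a median of 0.23, although IFI27 and BST2 differed by 1.21 and 0.69. There 131 of the 136 genes were still lower, by a median of -0.42, and at number 1 the median was -0.44. Between these pairs the decrease did not follow the size of the interferon difference. Number 3 is 1 pair of arrays without a spread, so the interferon response as the whole cause is not excluded. COUP-TFII siRNA array 2, where the decrease was largest, was argued against as the whole cause by the differences at the other numbers (median -0.43, 134 of 136 lower). An effect of COUP-TFII on proliferation may account for the pattern as a hypothesis. A difference in growth between the cultures or an effect of the COUP-TFII siRNA on other transcripts was not tested.

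Lysosomal protein genes, a family chosen after the data were seen, had a median log2 fold change of 0.31 over 43 genes. A trend with signal level was argued against by 10000 random lists matched on mean signal, whose median was 0.0123 and whose highest was 0.18. A difference in scale between the arrays was argued against by quantile normalization, which left a median of 0.29. At number 3, where interferon-stimulated genes differed less, 35 of the 43 genes were higher, with a median of 0.31, against 0.25 at number 1. Number 3 is 1 pair of arrays without a spread, so the interferon response as the whole cause is not excluded. Fewer dividing cells or an effect of COUP-TFII may also account for the higher lysosomal genes as hypotheses, which these arrays cannot separate.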

How the results depend on the processing

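Leaving out both arrays of a number was chosen only after the results were seen; all other alternatives were planned. Over 21 settings that refit all genes, 35 of the 83 named genes past the threshold kept the call in every setting that gave them a value, 26 of them with a value in all, and 48 lost it in at least 1. Only 72 of the 94 named genes had a value on probe sets without a letter suffix. Of the 94 named genes, 4 changed sign in at least 1 setting. Of all values for named genes, 1707 kept direction and side of the threshold, 217 fell short of it, 13 newly passed and 7 reversed, and for gene lists these counts were 410, 32, 11 and 7. Leaving out a single array ended 25, 28 and 14 calls of named genes for control array 1, 2 and 3 and 15, 13 and 6 for COUP-TFII siRNA array 1, 2 and 3. Over these 6 fits the genes that rose numbered 721 to 1437 and those that fell 382 to 1066, PROX1 differed by -0.12 to 0.20 and the venous median was -0.14 to 0.051. With both arrays numbered 1 left out, 404 genes rose and 240 fell, and with both numbered 2 left out, 544 and 310; fewer arrays remain in these fits. The venous median was then 0.0057 and 0.028, and that of blood cell markers 0.011 without number 2, where its camera direction turned. The replicate block raised the number that fell to 1715. It changed the calls of HEY1, HEY2, JAG1, CDK2, LYVE1 and the inflammatory list, and no other call of a named gene or list. A fold of at least 1.5, by construction stricter, left 530 and 431 genes. Quantile normalization gave 1403 and 1391, of which 1382 and 1125 were called without it. With an estimated correlation camera called 0 lists, of which 2 had an unadjusted p under 0.05, where fry called 11. By fry mitosis (adjusted p = 0.0590), interferon (0.246), cholesterol (0.411) and stress genes (0.409) lost the call, and cyclin-dependent kinase inhibitors (0.0197), nuclear receptors (0.0129), smooth muscle (0.0388) and epithelial markers (0.0412) passed. Over all alternatives the adjusted p of the first 4 lists ranged up to 0.343, 0.552, 0.663 and 0.701, and that of the last 4 from 0.0197 to 0.708, 0.0129 to 0.555, 0.0388 to 0.815 and 0.0412 to 0.773. Only probe sets without a letter suffix gave 7 lists, GINS2 at 0.095, TGFB1 at -0.17 and an epithelial median of -0.033. The mean of probe sets gave NRP1 at 0.17 and PROX1 at -0.017, and ended the calls of 11 named genes. The lymphatic list turned direction with the lowest 60% of probe sets left out (median 0.059), and the venous list by fry (median -0.0057). For these changes of direction the cause was not tested. Over all probe sets without a bound, 98.0% of the authors' listed probe sets passed limma in the direction of their group means, against 84.2% of listed genes in the main comparison, which covers 1 probe set per gene. The targeted transcript gave no value under any setting, since none of the annotated probe sets used here carries its name. Dim genes are limited by the signal over background, since those below the bound were not tested.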

Other observations

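The gene families here and every test of them were chosen only after the results were seen. Genes of lysosomes and autophagy were higher after COUP-TFII siRNA. Of 43 lysosomal protein genes tested, 21 rose and 2 fell by limma, with medians of 0.25, 0.37 and 0.31 in the 3 same-numbered pairs. The lysosomal protease genes TPP1 and CTSB rose by 0.84 ± 0.09 and 0.53 ± 0.09 (SE, n = 3 arrays per group, limma adjusted p = 0.000785 and 0.00421), and the membrane protein gene LAMP1 by 0.35 ± 0.06. CTSK, a cathepsin gene, changed by -0.48 ± 0.09. Of 34 autophagy genes 9 rose and none fell by limma (1 was lower at an unadjusted p under 0.05), among them FYCO1, an adaptor for autophagosome transport, by 1.41 ± 0.11, MAP1LC3B by 0.89 ± 0.09 and GABARAP by 0.61 ± 0.07, besides WIPI1. TPP1, CTSB, LAMP1, CTSK, FYCO1, MAP1LC3B, GABARAP and WIPI1 kept their limma calls on leaving out any single array. Other called members did not, such as MCOLN1, which lost its call in each of the 6 fits. CTSH and GABARAPL1 lost it in 5 of them and ATG2A in 1. Limma's camera gave adjusted p-values of 1.16e-07 and 0.00255 over 9 families, and both calls were lost at adjusted p = 0.248 with an estimated correlation. The adjustment does not cover the choice of the 9 families on these same values, so their p-values only describe them. The number of lysosomal genes that rose was 12 without control array 1 and 12 without control array 2.

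Genes of RNA splicing and of the mitochondrial ribosome were lower. Of 38 splicing factor genes of the SRSF, HNRNP and SF3 families, 13 fell and none rose by limma (24 were lower and 0 higher at an unadjusted p under 0.05), with a median of -0.18. HNRNPA3, HNRNPH3 and SRSF4 changed by -0.60 ± 0.11, -0.47 ± 0.08 and -0.39 ± 0.06 (SE, n = 3 arrays per group, limma adjusted p = 0.00691, 0.00476 and 0.00381). Of 10000 random lists matched on mean signal, 0 had a median as low, and the lowest was -0.14. The random lists ignore correlation between genes, and the family was chosen on these same values, so this count is not a p-value. Of 74 mitochondrial ribosomal protein genes 15 fell and 2 rose, with a median of -0.15. MRPS35 changed by -0.63 ± 0.10 and MRPL36 rose by 0.67 ± 0.07. Limma's camera adjusted p-values were 2.48e-09 and 1.16e-07, and both calls were lost, at adjusted p = 0.248 and 0.290 with an estimated correlation. Without control array 1 or 2, 5 and 6 splicing factor genes and 2 and 2 mitochondrial ribosomal genes fell, and the latter count was 5 without COUP-TFII siRNA array 2 and 9 without array 1 or 3 of that group. The direction of these 4 families was kept under quantile normalization and median scaling and without each array.

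The other 5 families did not pass on all 6 arrays. Without control array 2 the integrin and proton pump families passed (limma's camera adjusted p = 0.0492 each, and up to 0.189 and 0.263 over both scalings, the block and single arrays left out). With an estimated correlation their adjusted p-values without that array were 0.307 and 0.322, and on all arrays 0.248 and 0.398. Without control array 2, 5 collagen and 5 integrin genes rose. Of 26 collagen genes 8 rose and 1 fell (limma's camera adjusted p = 0.0789), with COL5A1 rising by 0.94 ± 0.14 and COL8A2 by 0.77 ± 0.09. Of 21 integrin genes 8 rose and 2 fell (limma's camera adjusted p = 0.0866), with ITGA3 and ITGB5 rising by 0.89 ± 0.13 and 0.69 ± 0.06 beside ITGB3, and ITGB8 the largest decrease. The integrin family was narrowed to receptor subunits after a first, wider pattern had been tested. By that pattern 8 of 25 genes rose and 4 fell, and limma's camera gave an adjusted p of 0.469 on all arrays and 0.244 without control array 2, so the call of this family depends on the choice. Of 16 subunits of the vacuolar proton pump 3 rose and none fell, with 1 lower at an unadjusted p under 0.05 (limma's camera adjusted p = 0.0866). Cytoplasmic ribosomal protein genes (52 tested, 1 rose and 1 fell, median 0.0036, and -0.0095 after quantile normalization) and proteasome subunits (33 tested, 3 rose and 2 fell, median 0.02, and -0.0017 after quantile normalization) had limma's camera adjusted p-values of 0.776 and 0.516. For proteasome subunits 1 rose and 0 fell by limma without control array 1 and also without control array 2 (2 were lower each time at an unadjusted p under 0.05), while 5 rose without COUP-TFII siRNA array 3 and 5 with the replicate block.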
